A study of Danio rerio with 15 samples.

How the data were processed

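Gene expression was measured by RNA sequencing in heads of zebrafish (Danio rerio) embryos at 2 days post-fertilization. Per the labels' protocols, each library came from a pool of 20 embryos reared at 28 °C. Messenger RNA was captured with oligo-dT beads, prepared with a stranded kit and sequenced as 50 bp single-end reads, with 5 libraries per lane and about 66 M reads (M, mega) stated per sample. The lane of each library is not given in the sources used here, so lane and group cannot be told apart. The labels name 15 samples in 3 groups of 5, namely embryos injected with the dye phenol red, with a guide RNA against ncapg2 alone, or with that guide RNA plus Cas9. The series design calls these biological replicates, so p-values measure the spread between pools of embryos. The number given to the guide RNA differs between the sample titles and the treatment labels, and it is called the guide RNA here.

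The authors deposited 3 tables, each for a pair of groups with 10 libraries. Per the submitters' processing notes, bcl2fastq, Trim Galore, cutadapt, STAR, HTSeq and DESeq2 were used. Their versions, order and settings, the genome build, the annotation release and the strand setting of the counting are not given in the sources used here. For each library, the authors deposited a normalized signal per gene, that is a gene count divided by 1 size factor per library. A library held the same values in each table that contained it (largest difference 0). The tables also hold the authors' log2 fold changes with their standard errors, a test statistic (unit score) and p-values, as deposited. The 3 tables shared 23009 genes with identifiers and names as the authors deposited them, and 493 genes had no name. Library columns were assigned to groups by the pair of tables that held them. The columns carry no replicate number, so libraries are called S1 to S15 by their column headings.

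Within a library, every value was a whole multiple of the smallest value above 0 within a tolerance of 0.001 of a read (100% of values). Division by that step gave whole reads, which totalled between 34.97 and 49.3 M per library. Where a gene shares reads with a near-identical copy, the authors' counting could split them, and such values are uncertain.

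Because the tables held normalized values, limma 3.58.1 in R 4.3.3 was used as fixed before the data were examined. The limma trend method with robust empirical Bayes moderation was fitted to log2(value + 1) for the 2 groups compared. Genes entered with a value of 10 or more in at least 5 libraries of the comparison. Adjusted p is Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. For ncapg2 a two-sided exact permutation test of mean log2 values was added. Fixed lists of genes, 29 in number with 818 of 882 symbols matched, were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The results of 1 list, which was in this adjustment, are not reported here. Symbols missing from the tables were looked up among the synonyms of a RefSeq table of assembly GRCz12tu, from which no coordinates were taken. A list's score in a library is the mean over its members of the log2 value minus the gene's mean over the 15 libraries.

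Named genes followed a rule fixed with the design. It takes ncapg2 always, and the 10 largest rises and 10 largest falls among called genes for guide RNA plus Cas9 against guide RNA, or 5 of each for the other comparisons. These needed a mean of 50 or more and groups that did not overlap. From each list described beyond its counts, it takes up to 4 members with the smallest adjusted p, ties being ordered by p. Genes with clone-style names were counted and not named, apart from those stated to have been chosen after their values were seen.

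The steps were tested on simulated data with 200 changed genes, drawn from the real means, dispersions and library sizes. For guide RNA plus Cas9 against guide RNA (21446 genes in that step), limma recovered 14% of genes changed 1.25-fold, 72% at 1.5-fold, 92% at 2-fold and 98% at 4-fold, with 5 false calls. Known changes were also multiplied into the real values of 200 genes in 10 draws for that comparison (21590 genes), and 28.2% were called at 1.25-fold, 78% at 1.5-fold and 94.4% at 2-fold.

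Alternatives were TMM rescaling, DESeq2 1.42.0 on the recovered reads, no filter and a filter of 50, pseudocounts of 0.5, 5 and 10, all 3 groups in 1 fit, each library left out, non-robust moderation, sample weights and stricter thresholds. After seeing the data, edgeR 4.0.16 (quasi-likelihood, on the recovered reads), a block of library sets and the removal of a library set were added. The sets were found from the values, without using the column order, as the grouping of 1 library per group into 5 sets, among 14400 ways, with the highest summed correlation of deviations from the group means. The mean correlation within sets was 0.52, against 0.43 for the next best way and a median over all ways of -0.01. All 15 libraries fell in the same sets when either random part of the genes was used. All 15 libraries also stood in the set of their place in the order of their group's column numbers, as 1 of the 14400 ways does, although the labels do not say that this order pairs libraries. Because the sets were chosen from the same values that were then tested, the blocked p-values may be too small.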

Results

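RNA was measured in 15 pools of zebrafish embryo heads at 2 days post-fertilization, 5 per group. The groups were injected with phenol red, a tracer dye, with a guide RNA against ncapg2, or with the guide RNA plus the Cas9 nuclease that it directs to the gene. NCAPG2 is a subunit of condensin II, a complex that compacts chromosomes for cell division. The recovered reads assigned to genes ranged from 34.97 to 46.46 M (M, mega) per library for phenol red, from 39.79 to 49.3 M for guide RNA and from 41.58 to 48.51 M for guide RNA plus Cas9. The stated purpose was to see the effect of losing NCAPG2 on the transcriptome of the developing head.

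The targeted gene, ncapg2 (ENSDARG00000060023), was lower in every library of guide RNA plus Cas9 than in any library of the other groups. Its normalized count was 428 ± 48.4 (SD, n = 5) with guide RNA plus Cas9, 912 ± 73.7 (SD, n = 5) with guide RNA alone and 856 ± 69.7 (SD, n = 5) with phenol red. The level with Cas9 was thus 46.9% of that with guide RNA and 50.02% of that with phenol red. Each difference gave p = 0.0079 in a two-sided exact permutation test with n = 5 per group, the smallest p that the 252 regroupings can give. Guide RNA alone and phenol red did not differ beyond the spread between pools (exact permutation p = 0.25, n = 5 per group).

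**Figure D1:**
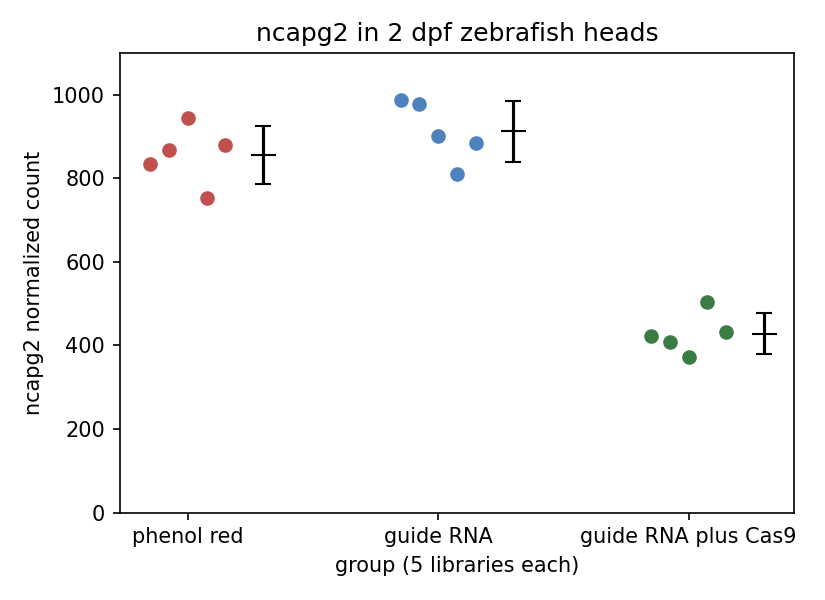
Normalized ncapg2 count (y axis) for each library (points) in the 3 groups (x axis), with the mean and SD of 5 libraries beside them. The guide RNA plus Cas9 libraries lie between 373 and 505, and those of the other groups between 754 and 988.

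The first comparison, guide RNA plus Cas9 against guide RNA, asks what Cas9 with the guide changed beyond injection of the guide. No group received Cas9 without this guide, so editing of ncapg2 and the presence of Cas9 cannot be told apart. Of 21590 genes tested, ncapg2 fell and no other gene was called. Its log2 fold change was -1.09 ± 0.08 (SE), with a limma adjusted p of 0.00032, and the authors' deposited table gives -1.09 ± 0.09 (SE) and also calls 1 gene. At an unadjusted p under 0.05 there were 76 genes higher and 122 lower, 0.92% of those tested, where chance gives 5%. edgeR and DESeq2 on the recovered reads each called 1 gene. Fitted by limma with a block for 5 sets of libraries that varied together (A to E), 983 genes (4.55%) reached an unadjusted p under 0.05, 465 of them higher, and 2 more genes were called lower, both named after their values were seen. They were rhcgl1, an ammonium transporter gene of the Rh family, at -0.78 ± 0.11 (SE; 0.66 without the block), and zgc:165423, at -0.53 ± 0.07 (SE; 0.18 without the block), and each was lower in 5 of 5 sets. The groups did not overlap for 50 genes, 0.23% of those tested against 0.79% by chance. The 95% interval lay within 2-fold for 95.03% of genes and within 1.5-fold for 85.6%.

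No condensin gene other than ncapg2 was called. Of 8 members tested, 1 was lower, none was higher and 7 were not called, and ncapg2 was also the 1 member called when adjusted over the list alone. The log2 fold change was -0.08 ± 0.06 (SE) for ncaph2, a condensin II subunit, 0.05 ± 0.07 for smc4, an ATPase shared by the condensins, and 0.04 ± 0.05 for ncapd2 of condensin I.

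Genes of the eye and of pigment cells had mostly positive fold changes, and none of them was called. The 28 lens genes had a median log2 fold change of 0.12, 25 of them positive (camera adjusted p = 4.5e-09; adjusted p = 0.52 with an estimated correlation). Among them the lens fibre connexin cx44.1 was at 0.16 ± 0.07 (SE), and the crystallins crybb1, cryba1b and cryba1a were at 0.31 ± 0.14, 0.23 ± 0.12 and 0.31 ± 0.18. The 35 retina and photoreceptor genes had a median of 0.07, 29 of them positive (camera adjusted p = 7.8e-06; adjusted p = 0.52 with an estimated correlation). Values were 0.09 ± 0.05 for bhlhe22, 0.20 ± 0.10 for otx5, 0.20 ± 0.12 for pou4f3 and 0.29 ± 0.17 for rho, which encodes rod opsin. The 23 pigment cell genes had a median of 0.08 (camera adjusted p = 0.00083; adjusted p = 0.52 with an estimated correlation), with the melanin synthesis genes tyrp1a at 0.26 ± 0.09 and tyr at 0.26 ± 0.10, oca2 at 0.26 ± 0.13 and pmela at 0.20 ± 0.11. Without guide RNA library S6 the mean difference in list score went from 0.127 to 0.064 for lens and from 0.084 to 0.049 for retina, and without Cas9 library S14 it was 0.083 for lens, 0.052 for retina and 0.052 for pigment cells, which then no longer passed camera. With library sets as a block, the lens genes crybb1l1, cryba1a, cryaa, cryba1b and crybb1, chosen after their values were seen, were called higher when adjusted over the list alone. Against phenol red, the Cas9 libraries gave lens genes a median of -0.02, with 12 of 28 positive (camera adjusted p = 0.85). Pigment cell genes had a median of 0.01 there, with 14 of 23 positive (camera adjusted p = 0.91). Retina genes, at a median of 0.09, passed camera there with the preset correlation and not with an estimated one. The lens and pigment differences were thus seen against guide RNA and not against phenol red.

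The 37 epidermis genes had a median of -0.05, 23 of them negative (camera adjusted p = 0.00043; adjusted p = 0.52 with an estimated correlation). The envoplakin gene evpla was at -0.15 ± 0.07 (SE), agr1 at -0.12 ± 0.06, and the claudin genes cldne and cldnh at -0.11 ± 0.05 and -0.11 ± 0.06. In all, 10 of 29 lists passed the camera test with the preset correlation, 8 toward higher and 2 toward lower values, and 0 passed with an estimated correlation (smallest adjusted p = 0.52). The others that passed were cranial neural crest and cartilage (median 0.09), proneural genes and Notch ligands (0.06), mitosis (0.04), neural progenitors (0.03), primary microcephaly genes (0.03) and, toward lower values, DNA replication (-0.03). Lens, retina and epidermis passed without each library in turn, and the other 7 lists did not pass without 1 or more of S6, S7, S8, S11, S12, S13, S14 and S15. The mean difference in score of mitosis went from 0.024 to 0.0062 without S8 and to 0.0083 without S11. Without S6 it went from 0.037 to 0.013 for neural progenitors (0.023 without S13 and 0.022 without S14) and from 0.052 to 0.023 for neural crest and cartilage, and without S7 from 0.053 to 0.032 for proneural genes. For DNA replication it went from -0.0385 to -0.022 without S11, -0.024 without S7 and -0.061 without S12, where the list still passed. The DNA replication list did not pass without S6 (-0.049), S14 (-0.0365) or S15 (-0.029). The mean difference was larger for neural crest without S9 (0.079) and for pigment cells without S7 (0.126) or S13 (0.142). With library sets as a block, primary microcephaly genes did not pass (camera adjusted p = 0.063). Lists without a call were condensin complexes, apoptosis, DNA damage response and repair, cohesin and SMC5/6, differentiated neurons, muscle, erythroid cells, macrophages and neutrophils, interferon and inflammation, the unfolded protein and integrated stress response, heat shock, immediate early genes, endothelium, hatching gland, posterior hox genes, yolk and liver, circadian clock and mitochondrially encoded genes. Apart from ncapg2, no member of the lists reported here was called without the block, over all genes or adjusted over the list alone. The yolk and liver score, which marks tissue from outside the head, ranged from -3.52 to 1.74 among the Cas9 libraries and from -0.95 to 1.87 among the guide RNA libraries.

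**Figure D2:**
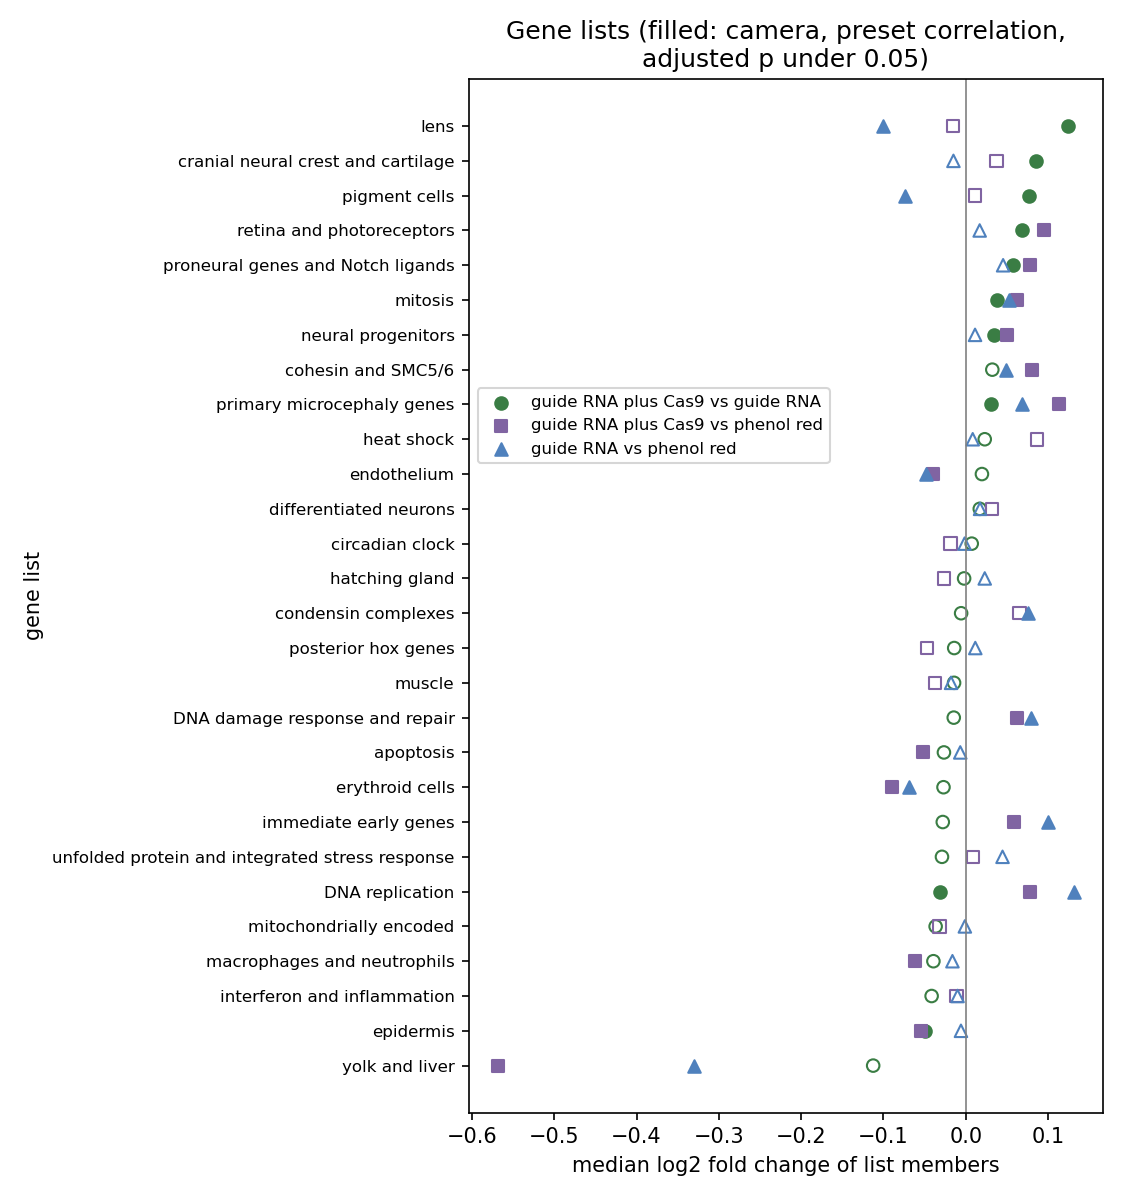
Median log2 fold change of the members of each gene list reported here (x axis, one line per list) in the 3 comparisons (symbols). Filled symbols mark lists that passed camera at an adjusted p under 0.05 with the preset correlation, and no list passed with an estimated correlation. The medians lie between -0.57 and 0.13.

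The second comparison set guide RNA plus Cas9 against phenol red, which differs by guide and nuclease together. Of 21580 genes, ncapg2 fell by 1.001 on the log2 scale (SE 0.09, limma adjusted p = 0.00087) and no other gene was called. edgeR called 1 gene and DESeq2 called 2, and the authors' deposited table also calls 2. Its other gene is si:dkey-204l11.1, chosen here after its values were seen, with a log2 fold change of 0.91 and an adjusted p of 0.0038 in the authors' deposited table. In the limma fit it was at 0.90 ± 0.17 (SE), with normalized counts of 127 ± 20.8 (SD, n = 5) and 68.1 ± 13.3 (SD, n = 5), and was not called. Against guide RNA, with a normalized count of 76.4 ± 11.8 (SD, n = 5), its limma log2 fold change was 0.72 ± 0.15 (SE), also not called, and it was 0.18 ± 0.17 for guide RNA against phenol red. At an unadjusted p under 0.05, 314 genes were higher and 181 lower, 2.29% of those tested. The block of library sets gave 1969 (9.12%), 1339 of them higher, and the unnamed gene ENSDARG00000078683, chosen after its values were seen, was called higher at 0.63 ± 0.08 (SE; 0.14 without the block) and was higher in 5 of 5 sets. The 95% interval lay within 2-fold for 94.9% of genes.

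Of 8 condensin genes, ncapg2 was lower and 7 were not called, with a median of 0.07 and a mean of -0.04. Values were 0.25 ± 0.12 for smc4, 0.17 ± 0.09 for ncapd2 and 0.08 ± 0.07 for ncaph.

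Cell division genes had mostly positive fold changes, and none was called. The 49 mitosis genes had a median of 0.06, 39 of them positive (camera adjusted p = 2.2e-06; adjusted p = 0.37 with an estimated correlation). The cytokinesis genes ect2, prc1a and racgap1 were at 0.25 ± 0.07 (SE), 0.14 ± 0.05 and 0.14 ± 0.06, and the cohesin protector gene sgol1 at 0.20 ± 0.07. The 16 primary microcephaly genes had a median of 0.11, 14 of them positive (camera adjusted p = 0.00053; adjusted p = 0.37 with an estimated correlation). Here phc1 was at 0.18 ± 0.06, cep152 at 0.15 ± 0.06, cenpe at 0.17 ± 0.10 and aspm at 0.13 ± 0.08. The 23 proneural genes and Notch ligands had a median of 0.08 (camera adjusted p = 0.00084; adjusted p = 0.44 with an estimated correlation), with insm1b at 0.22 ± 0.08, onecutl at 0.19 ± 0.08, onecut1 at 0.20 ± 0.08 and neurog1 at 0.16 ± 0.09. The 37 epidermis genes had a median of -0.05, 33 of them negative (camera adjusted p = 7.3e-05; adjusted p = 0.37 with an estimated correlation), with agr1 at -0.16 ± 0.06, epcam at -0.13 ± 0.07, cldne at -0.09 ± 0.06 and cldnh at -0.12 ± 0.07. With the preset correlation 15 of 29 lists passed, 9 toward higher and 6 toward lower values, and 0 passed with an estimated correlation (smallest adjusted p = 0.37). The others were DNA replication (median 0.08), cohesin and SMC5/6 (0.08), DNA damage response and repair (0.06), retina and photoreceptors (0.09), neural progenitors (0.05) and immediate early genes (0.06), and, toward lower values, apoptosis (-0.05), erythroid cells (-0.09), macrophages and neutrophils (-0.06), endothelium (-0.04) and yolk and liver (-0.57). Scores of the yolk and liver list ranged from -1.16 to 2.11 among the phenol red libraries, and its mean difference, -0.62, was 0.20 without Cas9 library S14, so that the sign reversed, and -0.19 without phenol red library S1. Without S1 the difference went from 0.082 to 0.035 for DNA replication and from 0.088 to 0.042 for proneural genes, which still passed. It went from 0.072 to 0.024 for cohesin and SMC5/6, from 0.078 to 0.021 for retina, from 0.059 to 0.035 for neural progenitors, from -0.047 to -0.015 for apoptosis and from -0.066 to 0.023 for erythroid cells, and these did not pass. Without S11 it went from 0.072 to 0.0006 for immediate early genes (0.045 without S5, 0.119 without S1 and 0.109 without S13) and from 0.066 to 0.041 for DNA damage response and repair. It went from -0.060 to -0.0026 for macrophages and neutrophils without S15 (-0.025 without S1 and -0.105 without S12). Without S14 it was -0.0007 for erythroid cells, 0.047 for retina and -0.018 for endothelium, which was at -0.035 with all libraries, -0.021 without S1 and -0.060 without S12. Erythroid cells were at -0.026 without S2, -0.037 without S13, and between -0.155 and -0.123 without S4, S5 or S11. Apoptosis was at -0.0725 without S4, and yolk and liver at -0.40 without S15 and between -1.12 and -0.98 without S2, S11 or S12. Mitosis, DNA replication, primary microcephaly genes, proneural genes and epidermis passed without each library in turn, and the other 10 lists did not pass without 1 or more of S1, S2, S3, S4, S5, S11, S13, S14 and S15. With library sets as a block, 6 members of the lists reported here were called when adjusted over the list alone, ncapg2 and nt5c2l1 lower and smc4, ncapd2, ect2 and insm1b higher, and heat shock genes passed camera (adjusted p = 0.021; adjusted p = 0.54 with an estimated correlation).

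The third comparison, guide RNA against phenol red, gives the background of injecting a guide without nuclease. None of 21601 genes was called by limma, and edgeR, DESeq2 and the authors' deposited table also called 0. At an unadjusted p under 0.05, 112 genes were higher and 112 lower, 1.04% of those tested by limma, against 221 genes by edgeR and 229 by DESeq2. When library sets were a block, limma called 4 genes, all lower, and 1665 genes (7.71%) reached an unadjusted p under 0.05, 1072 of them higher, so the even balance was not kept. The 95% interval lay within 2-fold for 94.7% of genes. The log2 fold change of ncapg2 was 0.09 ± 0.08 (SE).

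DNA replication genes had mostly positive and lens genes negative fold changes, and none was called. The 39 DNA replication genes had a median log2 fold change of 0.13, 37 of them positive (camera adjusted p = 8.4e-14; adjusted p = 0.23 with an estimated correlation). The helicase genes mcm3, mcm5 and mcm4 were at 0.21 ± 0.08 (SE), 0.16 ± 0.07 and 0.21 ± 0.09, and the chromatin assembly gene chaf1b at 0.17 ± 0.08. All 28 lens genes were negative, with a median of -0.10 (camera adjusted p = 3.5e-12; adjusted p = 0.36 with an estimated correlation). Among them cx44.1 was at -0.20 ± 0.07, bfsp2 at -0.16 ± 0.09, cryba1b at -0.19 ± 0.11 and crybb1l2 at -0.15 ± 0.09. The 23 pigment cell genes had a median of -0.07 (camera adjusted p = 0.0064; adjusted p = 0.71 with an estimated correlation), with dct at -0.25 ± 0.12, tyrp1a at -0.22 ± 0.10, oca2 at -0.25 ± 0.13 and pmela at -0.24 ± 0.13. All 8 condensin genes were positive, with a median of 0.08 (camera adjusted p = 0.0012; adjusted p = 0.36 with an estimated correlation), and smc4 was at 0.20 ± 0.12, ncapd2 at 0.14 ± 0.09 and ncapd3 at 0.08 ± 0.07. The lens and pigment medians thus had the opposite sign to those of Cas9 against guide RNA, and these comparisons share the guide RNA libraries, so that a chance value in that group moves both in opposite ways. With the preset correlation 12 of 29 lists passed, 7 toward higher and 5 toward lower values, and 0 passed with an estimated correlation (smallest adjusted p = 0.23). The others were immediate early genes (median 0.10), DNA damage response and repair (0.08), primary microcephaly genes (0.07), mitosis (0.05) and cohesin and SMC5/6 (0.05), and, toward lower values, yolk and liver (-0.33), erythroid cells (-0.07) and endothelium (-0.05). Condensin complexes, DNA damage response and repair, mitosis, DNA replication and lens passed without each library in turn. The other 7 lists did not pass without 1 or more of S1, S2, S4, S6, S7, S8, S9 and S10. The mean difference in list score of pigment cells went from -0.076 to -0.0015 without phenol red library S2, that of lens from -0.118 to -0.055 without guide RNA library S6, and those of DNA replication and condensin complexes from 0.120 to 0.073 and from 0.092 to 0.052 without S1. Erythroid cells, at -0.034, turned positive without S1 (0.055), S2 (0.0066) or S9 (0.0082), and were at -0.0094 without S8 and between -0.105 and -0.091 without S4, S5 or S6. Yolk and liver went from -0.56 to -0.13 without S1, to -0.37 without S9, to -0.36 without S10, to -0.95 without S2 and to -1.07 without S6. Without S1 cohesin and SMC5/6 also went from 0.049 to 0.0013 and primary microcephaly genes from 0.058 to 0.026. Immediate early genes went from 0.115 to 0.012 and DNA damage response and repair from 0.080 to 0.049 without S6, and endothelium from -0.033 to -0.012 without S10. Immediate early genes were at 0.055 without S7 and 0.192 without S10, endothelium at -0.019 without S1 and -0.055 without S7, and pigment cells at -0.118 without S7. No list member was called when adjusted over the list alone without the block. The block gave 16. In pigment cells dct, tyrp1a, oca2, pmela and slc45a2 were lower and trpm1a was higher (0.17 ± 0.06 SE). Elsewhere cx44.1, bfsp2, rpe65a, nt5c2l1 and csf1rb were lower, and mcm3, notch1a, notch1b, mpx and vwf were higher. The unfolded protein and integrated stress response then passed camera (adjusted p = 0.034; adjusted p = 0.49 with an estimated correlation).

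The comparisons of Cas9 with each control shared 1 called gene in the same direction, ncapg2, among 21497 genes tested in both. In 50 simulations of unchanged groups the highest shared count was 0, and 1 call in each of independent lists would share 4.7e-05. Across all genes, which are not independent replicates, the fold changes had a correlation of 0.50, against 0.52 simulated with unchanged groups and shared Cas9 libraries. The covariance was 0.0084 observed and 0.022 simulated. The simulated libraries were drawn independently, without the variation that libraries of different groups shared. When the Cas9 libraries were split between the comparisons, the shared count was 1 in 11 of 20 splits and 0 in the rest, and the mean correlation was -0.31. Each control kept a library of every library set, while each part of the Cas9 libraries held only some sets. Variation shared by sets then moves the parts in opposite ways, which alone makes this correlation negative. It therefore cannot show whether effects of Cas9 repeat.

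Libraries of different groups varied together. The deviations from the group means grouped the 15 libraries into 5 sets of 3, each with 1 library of each group (A is S1, S6 and S11, B is S2, S7 and S12, C is S3, S8 and S13, D is S4, S9 and S14, and E is S5, S10 and S15). Correlations across genes between libraries of a set lay between 0.13 and 0.78, and those between sets, in different groups, had a median of -0.12 and a highest value of 0.36. Library S12 had a higher correlation with S1 and S6 of set A (0.22 and 0.24) than with S2 of its own set (0.13). Library S2 in turn had higher correlations with S14 (0.36), S10 (0.22) and S15 (0.15) of other sets than with S12, and S14 had a higher correlation with S2 (0.36) than with S4 of its own set (0.34). With these sets as a block, an alternative added after seeing the data, ncapg2 was again called in both comparisons with Cas9 (log2 fold change -1.09 and -1.001). The counts of called genes became 3, all lower, for Cas9 against guide RNA, 2, with 1 higher and 1 lower, for Cas9 against phenol red, and 4, all lower, for guide RNA against phenol red. Without set A the counts were 1, 1 and 0.

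**Figure D3:**
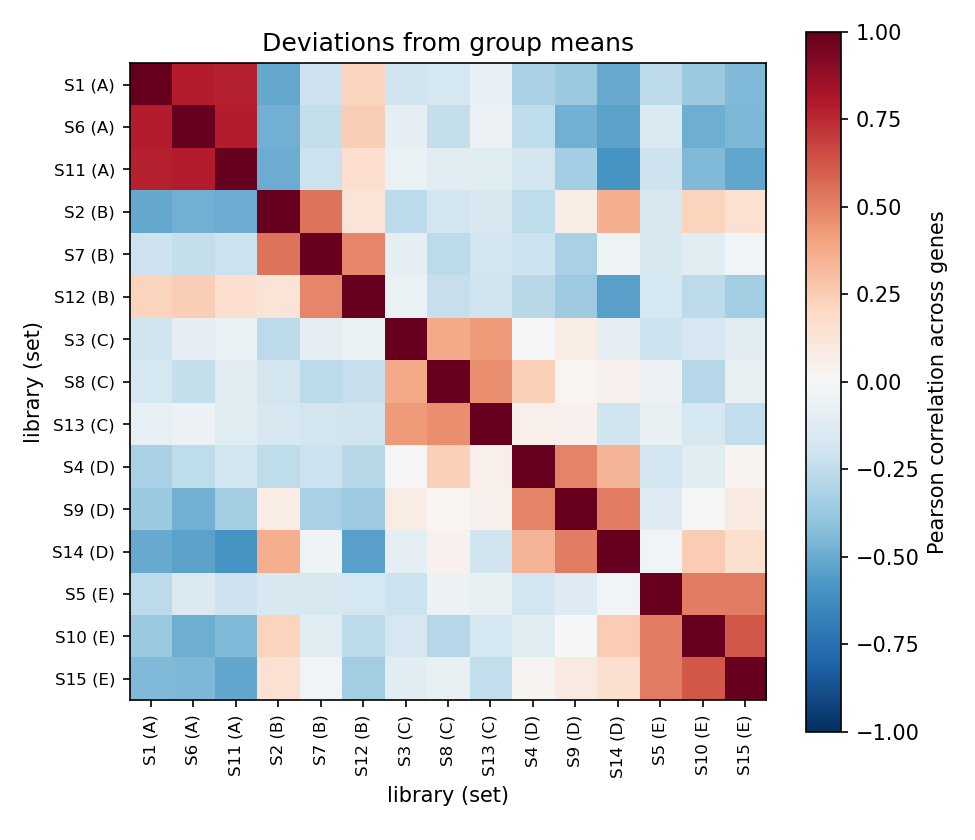
Pearson correlation across genes (colour) of deviations from the group means for each pair of the 15 libraries, ordered by set (letter in brackets). Squares of 3 libraries along the diagonal, with values between 0.13 and 0.78, are the sets.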

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

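The splits that keep library sets whole and the splits balanced over library sets were chosen only after results were seen. Each group of 5 libraries was checked for a library far from the others in depth, in ncapg2 and in the 29 list scores. This gave 4 cases among 93 groups of values, where chance gives about 1 in 20 groups, or 4.65. In phenol red, library S5 had 46.46 M reads, against 37.08 M for the next. Its library S1 had a cohesin and SMC5/6 score of -0.231, with the next at -0.03, and library S2 had a pigment cell score of 0.3199, with the next at -0.02. Among the guide RNA libraries, S6 had a yolk and liver score of 1.873, with the next at -0.28. Libraries S1 and S11, which fell in the same set as S6, had yolk and liver scores of 2.11 and 1.74.

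The counts of called genes and lists were set beside other splits of the same 10 libraries into groups of 5, with 100 splits drawn. The real split is included in each number. For Cas9 against guide RNA the real split called 1 gene, 4 of 100 splits called as many, and the highest other called 3. That share is under 0.05 among the splits drawn. The draw ignores the library sets and missed the split with the highest count given next, so it cannot exclude chance for this count. Of the 30 splits that keep 2 library sets whole, 5 called at least 1 gene and the highest called 2638 (sets A and B with S10 against the rest). Such splits put whole sets on the same side, which the real groups do not, so they show the structure of the samples and do not test the ncapg2 call. For Cas9 against phenol red 5 of 100 splits called the real 1 gene or more, with a highest other of 483, so chance cannot be excluded for the count by these splits, which ignore the library sets. The 483 came from a split with sets A and B whole. For guide RNA against phenol red the real count was 0, which all 100 splits reached, with a highest other of 889. Splits calling so many genes point to a structure of the samples, and the highest in each comparison put sets A and B, or A and E, on the same side. Splits with 1 library of each set on each side, as in the real groups, number 16, too few for a share under 0.05. Without a block the real count of 1 gene was reached by 1 of them, the real split itself, in each Cas9 comparison, where the highest other called 0, and for guide RNA against phenol red the real count of 0 was reached by all 16, with a highest other of 1.

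The list counts with the preset correlation were reached by many splits. For Cas9 against guide RNA the real split called 10 lists, 43 of 100 splits called as many, and the highest other called 17. The numbers were 15 lists, 13 splits and 20 for Cas9 against phenol red, and 12 lists, 36 splits and 19 for guide RNA against phenol red. Chance cannot be excluded for any of these list counts.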

How the results depend on the processing

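The edgeR fits, the block of library sets, the removal of set A and the list scores with a library left out were chosen after seeing the data. No paired analysis was possible with the labels' replicate numbers because the columns carry none; the library sets matched the order of the column numbers for 15 of 15 libraries, a hint from the files and not from the labels. The fall of ncapg2 with Cas9 kept its direction and its call under every alternative that kept at least 4 libraries per group, though with the Cas9 libraries split between the comparisons, which leaves fewer samples, the shared call was made in 11 of 20 splits and 0 calls were shared in the rest. It had log2 fold changes between -1.15 and -1.05 against guide RNA, and between -1.06 and -0.95 against phenol red, when each library was left out. The count of called genes stayed at 1, 1 and 0 under rescaling, filters, pseudocounts, thresholds, sample weights and each left-out library, except that DESeq2 called 2 for Cas9 against phenol red; the cause was not tested. With library sets as a block, limma and edgeR each called 3, 2 and 4 genes; the cause was not tested here. Gene lists depended on the test: with an estimated correlation 0 passed in each comparison. When each library was left out, between 6 and 14 lists passed for Cas9 against guide RNA (6 without guide RNA library S7), between 10 and 18 for Cas9 against phenol red (10 without phenol red library S1), and between 7 and 14 for guide RNA against phenol red (7 without guide RNA library S10), where 10, 15 and 12 were reported. Without set A, 6, 14 and 8 passed. The 61 other values taken by the rule for named genes kept their sign in all 1463 refits, and 0 of them passed the threshold. The rule took list members with the smallest adjusted p in these same data, and the refits reuse the same libraries. The kept signs are therefore no independent support for these differences. At this depth and spread, known 1.5-fold changes multiplied into the real values were called in 78% of cases for Cas9 against guide RNA and the smallest such changes in 28.2%, against 94.8% and 67.2% with library sets as a block. In fully simulated libraries for that comparison, with 21446 genes and no block, these changes were recovered in 72% and 14% of cases. Both tests changed 200 genes with a mean of 50 or more at once. Many true changes ease the Benjamini-Hochberg threshold, so these shares do not hold for a few isolated changes.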

Other observations

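The added lists of heart and retinal pigment epithelium genes, the library sets and the tests that use them were chosen after results were seen; the predictions for TMM rescaling, removal of set A, on and off genes, yolk adjustment and late-onset genes were written before their results.

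Heart genes had negative fold changes in guide RNA against phenol red. With library sets as a block, the 4 genes called for guide RNA against phenol red were all lower, and all were named after their values were seen. They were nppa, which encodes an atrial peptide (log2 fold change -0.67), vmhcl, a ventricular myosin (-0.40), rpe65a, the visual cycle isomerase of the retinal pigment epithelium (-0.47), and rbp2a, a retinol binding protein (-0.41). In a list of heart genes written afterwards, all 20 members were negative with a median of -0.30, and 0 were called without the block. All 12 measured genes of a retinal pigment epithelium list were negative with a median of -0.31, and 6 passed when adjusted over the list alone. These lists include genes that drew attention to them, so they are not independent evidence. The heart score was lower in 5 of 5 sets (sign-flip exact permutation p = 0.0625, the smallest that 5 sets can give). Against the same phenol red libraries, the Cas9 libraries gave heart and pigment epithelium medians of -0.34 and -0.19, which is not separate evidence, since fold changes of unchanged groups simulated with that shared control had a correlation of 0.51 across genes (0.63 observed) and a covariance of 0.022 (0.012 observed). For Cas9 against guide RNA, which share the guide, the heart median was 0.0022 with 9 of 19 members negative, and the pigment epithelium median was 0.13 with 10 of 12 positive and 0 called, opposite in sign to guide RNA against phenol red, with the guide RNA libraries in both.

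A candidate explanation is less trunk tissue left on the guide RNA heads, since the heart lies by the yolk. With the yolk and liver score as a covariate 73.8% of the heart difference was left, just short of the 75% set in advance as evidence against it, so this stays open. For pigment epithelium genes 112.8% was left. Their tissue lies in the eye and not in the trunk, so the covariate could not decide the question for that part. Slower development of guide RNA embryos was tested on 45 late-onset genes, of which 62.2% were negative, with a median of -0.02. That lies between the bounds set in advance (70% and 50%), so this cannot be told apart either, and an effect of the guide RNA itself stays open and untested.

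Fewer genes reached an unadjusted p under 0.05 than chance gives, in all 3 comparisons. The authors' normalization was tested by TMM rescaling, which left the share at 2.26% or less, and set A, which stands apart, by leaving it out, which left 1.91% or less. With the sets as a block the share rose to at least 4.55%, and 61.8% of the variance within groups was shared by sets on average over genes, against a mean of 32.5% and a highest of 52.1% for 100 random sets. With 20 random sets as a block the mean shares were 0.89%, 2.44% and 1.17%. The highest were 3.23%, 5.75% and 7.71%, against 4.55%, 9.12% and 7.71% with the real sets. The value of 7.71% was the same to every digit in both. A draw that repeated the real pairing of guide RNA and phenol red libraries would give this, so it is no separate comparison. Variation shared by sets may therefore make the tests without a block conservative, a hypothesis found and tested on the same data. Swaps of labels within sets number 16, too few for a share under 0.05: the real counts of 3, 2 and 4 genes were reached by 1, 3 and 2 labellings, the real one included, so by no other for Cas9 against guide RNA, with highest others of 1, 114 and 13.

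Some genes were on in all libraries of a set and off in all of another. With on set at 50 or more and off at under 5, there were 23 such genes, against a highest of 15 and a mean of 1.91 in 100 random sets, of which 0 gave as many, and 0 genes were on in all libraries of a group and off in all of another. The sets were chosen from these same values, so the comparison with random sets is not independent support for them. Of the genes, chosen after their values were seen, the class I histocompatibility gene mhc1uma is an example, as is 1 of the 2 genes named rrm2, which encode a ribonucleotide reductase subunit. That copy lay between 1.9 and 2.8 in set A and between 164.6 and 509.2 elsewhere, while the other copy was between 1236.7 and 1360 in set A and between 762.8 and 1003.6 elsewhere. Tissue carried along at dissection was tested only through the yolk and liver score. Of the 23 genes, 0% had an absolute correlation of 0.7 or more with that score, although the highest, 0.681, was close to that bound. This argues against carried yolk and liver tissue only, and other carried tissue was not tested. Different parents for each set, with reads shared between gene copies, may give such a pattern, but the labels name no parents and this was not tested further.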
